A study of Mus musculus with 24 samples.

How the data were processed

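Messenger RNA was sequenced from 24 retinas of C57BL/6 mice, an inbred laboratory strain, in 3 groups of 8. The labels give a first and a second air pressure for every mouse, in pounds per square inch (PSI), and a first pressure of 0 means that blast mice received a single wave. The sham group received 5 and then 5 PSI, the blast group 0 and then 20 PSI, and the preconditioned group 5 and then 20 PSI. The labels describe the 8 samples of a group as biological replicates. They give no sex, litter, batch or time of collection, and no pairing of samples across groups.

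Per the labels' protocols, RNA was extracted with a column kit and 500 ng of total RNA per sample went into a stranded, poly(A)-selected mRNA library. Per the submitters' processing notes, the tools were STAR 2.5.3a, featureCounts, Subread 1.5.2, R 3.3.2 and DESeq2, with the mouse build mm10. The authors deposited one table of whole-number read counts per gene, not normalized, with 53801 genes and 72 columns. Each of the 24 samples had 3 columns, which are repeat sequencing runs of one library. In the deposited counts, 81.6% of the run values from 1 to 20 were even, and a count of 2 (173129 values) was more frequent than a count of 1 (31809 values), so that most read pairs had been counted as 2 reads. Counting noise is therefore larger than a Poisson model of the deposited counts gives. The strand setting of the counting is not given in the sources used here, so values of genes that overlap an antisense partner are uncertain, and so are those of near-identical families such as the hemoglobin, histone and crystallin genes.

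The 3 runs of a library differed by a chi-square per degree of freedom of 2.13 to 2.24 over genes with at least 30 reads, and 2 libraries of the same group differed by 6.43 to 1314, and by at most 350 with blast replicate 6 left out. The runs were summed, and the sum counted as 1 replicate. Summed totals were 23.8 to 51.5 M (mega) counts per library, from runs of 7.0 to 18.4 M. Gene symbols and positions came from GENCODE vM21 on GRCm38, the assembly that mm10 names. They covered 53620 of the gene identifiers, and 181 had no symbol.

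Genes were tested with edgeR 4.0.16 (R 4.3.3). Genes were filtered with filterByExpr, library sizes were scaled with TMM, and all 3 groups entered a single robust quasi-likelihood fit with 1 coefficient per group and no covariate. Contrasts were tested with the quasi-likelihood F test and Benjamini-Hochberg adjustment over the 19905 genes tested, at a threshold of 0.05. CPM values are scaled with the TMM factors and given as mean ± SD over libraries. Log2 fold changes are given ± an approximate standard error, the absolute log2 fold change divided by the square root of its F statistic. Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over 41 lists that had at least 5 tested genes. The 43 lists covered the cell types of the retina, neighbouring eye tissues, immune cells and stress, metabolic and signalling pathways. Beside the preset correlation, camera with a correlation estimated per list, fry, and an exact two-sided permutation test of list scores (the mean log2 CPM of the members of a list) were run.

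The groups, contrasts, lists, tests and most alternatives were fixed before the data were examined. The rule for the genes named in the text was fixed then too. For a contrast with fewer than 5 genes past the threshold, it names the 10 with the smallest p, leaving out predicted genes, pseudogenes and sex-linked genes. In every contrast it also names Rbpms, Pou4f1, Pou4f2, Thy1, Sncg, Nefl, Gfap and Aif1, and 1 further gene that is not reported here.

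One library, blast replicate 6, differed from the other 23 in nearly all retinal markers. It stayed in the planned fit. After this was seen, every result was also computed without it, on 23 libraries and 20076 tested genes, and the rule for named genes was applied to that fit as well. The text says which fit each value comes from. The biological coefficient of variation was 0.426 with 24 libraries and 0.249 with 23.

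The pipeline was tested on simulated counts drawn from the means, dispersions and depths of the real libraries, with 50 genes changed at each of several folds. Changed genes were drawn only from those above a minimum mean CPM, so the shares below do not cover genes of low expression. No simulated library was an outlier, unlike blast replicate 6 in the real data. For blast against sham with 24 libraries, it recovered 4% of genes changed 1.2-fold, 56% of those changed 1.5-fold, 82% of those changed 2-fold and 90% of those changed 4-fold. With 23 libraries these shares were 12%, 88%, 94% and 96%. Of the calls, 2 of 118 and 3 of 148 were false. Of 4 lists shifted 1.3-fold, 3 and 4 were called, and no other list was. Simulated genes varied independently of each other. The simulation therefore does not show how often camera calls an unshifted list when its members vary together.

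Alternatives covered the scaling, the filter on low counts, DESeq2 1.42.0, voom with sample weights, the groups in the fit, a surrogate variable (sva 3.50.0), the threshold, a minimum fold of 1.2 and the omission of each library in turn. DESeq2 ran with its default settings, under which outlying counts are replaced in groups of this size. For fold changes that share the sham libraries, 100 simulations of unchanged groups and 100 random divisions of the sham group into sets of 4 were used. For counts of calls, 100 divisions of the libraries into groups of the same sizes were compared, the real one included. No deposited column was left unused.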

Results

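The data set consisted of retinal mRNA profiles from 24 mice. Of these, 8 were sham mice given 5 and then 5 PSI, 8 were blast mice given 0 and then 20 PSI, and 8 were preconditioned mice given 5 and then 20 PSI. The question named by the study is whether a low pressure wave before an injuring one alters the response of the retina, whose output neurons are the retinal ganglion cells. Library totals averaged 37.6 ± 6.94 M counts (M, mega) in the sham group, 33.6 ± 8.50 M in the blast group and 35.4 ± 4.53 M in the preconditioned group (SD, n = 8 each). P-values of genes and of exact permutation tests refer to the spread between mice. Those of camera compare the members of a list with the other genes tested. At the preset correlation they do not measure how list scores vary between mice.

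In 23 of the 24 libraries the profile was that of neural retina, with scores of the rod list (mean log2 CPM) from 10.45 to 11.02. In blast replicate 6 this score was 1.76, and genes of fibrillar collagen were among the most abundant. Col1a2 stood at 11249 CPM there, against 17.8 ± 14.3 CPM in the 7 other blast libraries (SD), and Col1a1 stood at 10507 CPM against 8.95 ± 13.0. Lyz2, a lysozyme of macrophages, stood at 5902 CPM against 10.6 ± 13.6, and the myelin gene Mbp at 2808 CPM against 37.2 ± 4.51. Relative to the 7 other blast libraries, the median member of the rod list lay at a log2 ratio of -9.51 in this library, of the cone list at -7.91, of the bipolar cell list at -7.53, of the retinal ganglion cell list at -3.98 and of the amacrine cell list at -3.92. The median member of the skeletal muscle list lay at 7.41, of the oligodendrocyte list at 6.24, of the fibroblast list at 6.11 and of the microglia list at 6.10. Its median Spearman correlation with the other libraries was 0.714 across genes, against at least 0.970 for the rest.

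**Figure D1:**
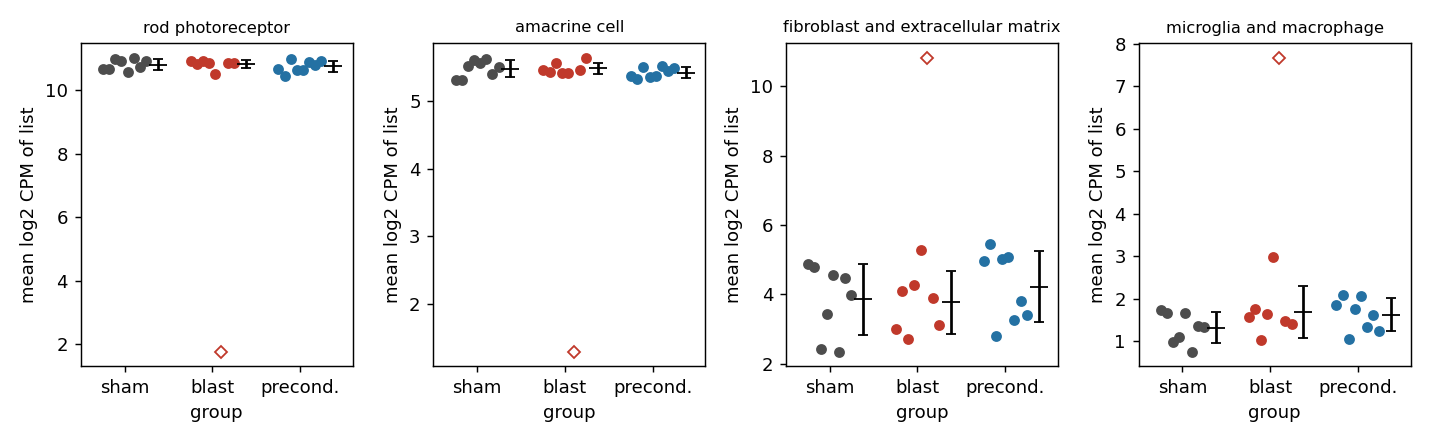
List scores per library (mean log2 CPM of the members) by group for 4 gene lists. Circles are libraries, the open diamond is blast replicate 6, and bars give mean ± SD without that library. Blast replicate 6 lies at 1.76 for rods, where the other blast libraries lie between 10.52 and 10.94, and at 10.82 for the fibroblast list.

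Crystallin genes, which encode the bulk proteins of the lens, took 1.23% to 11.2% of counts in 8 libraries and at most 0.0517% in the rest. These 8 were 3 sham, 2 blast and 3 preconditioned libraries.

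**Figure D2:**
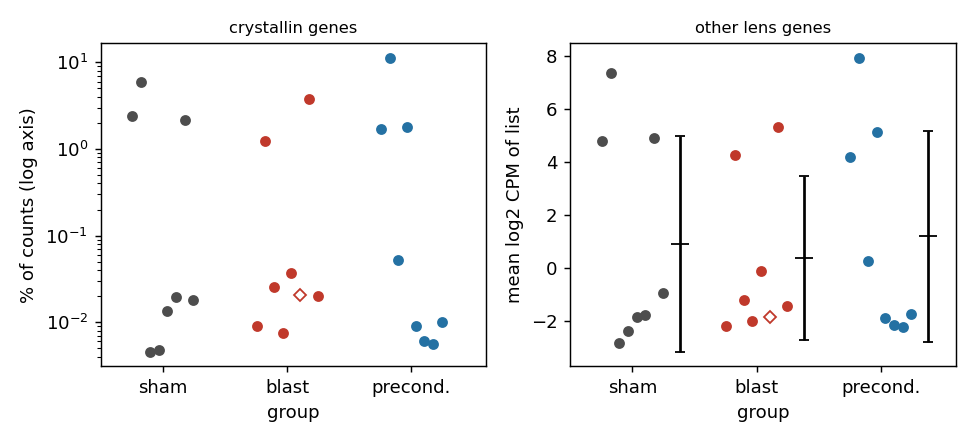
Share of counts from crystallin genes (percent, log axis) and score of the other lens genes (mean log2 CPM) per library, by group. Circles are libraries, the open diamond is blast replicate 6, and bars in the panel of other lens genes give mean ± SD without it. The 8 libraries above 1% crystallin are the 8 with the highest scores of other lens genes.

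Blast and sham retinas differed in both pressure waves, with 0 and then 20 PSI against 5 and then 5 PSI. The gene with the smallest p, with blast replicate 6 left out, was Ecel1, a neuronal membrane protease known to be induced by nerve injury. It measured 0.674 ± 0.222 CPM in sham retinas (SD, n = 8) and 2.85 ± 1.99 CPM in blast retinas (SD, n = 7). Its log2 fold change was 2.08 ± 0.39, and 6 of the 7 blast libraries lay above the highest sham library. Gfap, the intermediate filament of astrocytes and reactive Müller glia, measured 19.9 ± 5.91 and 29.1 ± 5.76 CPM, a log2 fold change of 0.55 ± 0.16. With all 24 libraries the log2 fold change was 1.90 ± 0.48 for Ecel1 and 3.35 ± 0.82 for Gfap (adjusted p = 0.126 each). The ganglion cell genes Rbpms, Pou4f1, Pou4f2, Thy1, Sncg and Nefl had log2 fold changes from -0.05 to 0.02 in the 23-library fit, with standard errors of 0.07 to 0.11, and from -0.22 to -0.01 with 24 libraries, with standard errors of 0.07 to 0.45. None of these differences passed the threshold in edgeR's quasi-likelihood test. The adjusted p was 0.434 for Ecel1 (unadjusted 2.16e-05) and 1.00 for Gfap.

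No gene passed in blast against sham retinas with all 24 libraries. The smallest adjusted p was 0.126, and 2497 genes had an unadjusted p under 0.05, 2315 of them higher in blast, against 995 by chance. With that library left out there was again no gene past the threshold, and 426 genes had an unadjusted p under 0.05 against 1004 by chance. DESeq2 called 0 genes with 24 libraries and 1 gene with 23, which was Ecel1, at an adjusted p of 0.00116. Over all alternatives the adjusted p of Ecel1 in this contrast ran from 0.00116 to 1.00. Ecel1 (ENSMUSG00000026247) lies on chromosome 1 from 87147655 to 87156521 and Gfap (ENSMUSG00000020932) on chromosome 11 from 102887336 to 102900912, both protein coding.

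With all 24 libraries, the 10 genes with the smallest p were Mmp12, Mpeg1, H19, Atp2a1, Itgb2, Tlr13, Ltf, Mag, Lox and Col10a1, with log2 fold changes from 4.85 to 7.79 and an adjusted p of 0.126 each in edgeR's test. These values rested on blast replicate 6. Atp2a1, a calcium pump of fast muscle, measured 0.812 ± 0.307 CPM in sham and 143 ± 403 CPM in the 8 blast libraries, but 0.791 ± 0.173 CPM in the 7 others. Its log2 fold change went from 7.45 ± 1.68 to -0.04 ± 0.24. For Mmp12, a macrophage elastase, it went from 7.17 ± 1.54 to 1.24 ± 0.40, for the integrin gene Itgb2 from 4.97 ± 1.12 to 0.80 ± 0.27, and for the macrophage perforin Mpeg1 from 4.85 ± 1.09 to 0.81 ± 0.26. For H19, Mag, Lox and Col10a1 the log2 fold change without that library lay between -0.02 and 0.40, for Tlr13 at 0.80 and for Ltf at 1.34. The microglial gene Aif1 had a log2 fold change of 3.12 ± 0.83 with 24 libraries and 0.35 ± 0.24 with 23.

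In the 23-library fit, the genes with the smallest p after Ecel1 were Ctss, Pcdh18, C1qb, Selplg, Adgrl4, Grin2c, Galnt1, Phtf1 and Gfap. Ctss, a lysosomal protease of microglia, had a log2 fold change of 0.56 ± 0.15, the complement gene C1qb 0.65 ± 0.18, the selectin ligand Selplg 0.45 ± 0.13 and the endothelial receptor Adgrl4 0.34 ± 0.10. The NMDA receptor subunit Grin2c had -0.37 ± 0.11, the protocadherin Pcdh18 -0.24 ± 0.07, Phtf1 -0.15 ± 0.04 and the glycosyltransferase Galnt1 0.12 ± 0.04. The adjusted p was 1.00 for each. With 24 libraries the log2 fold changes were 4.28 for Ctss, 3.72 for C1qb, 2.32 for Selplg, 1.61 for Adgrl4, 0.44 for Galnt1, 0.36 for Pcdh18, whose sign differed, -0.56 for Grin2c and -0.0084 for Phtf1. With blast replicate 5 left out beside blast replicate 6, Ctss stood at 0.34 ± 0.09, C1qb at 0.39 ± 0.13, Mpeg1 at 0.38 ± 0.15, Itgb2 at 0.46 ± 0.22, Ltf at 0.61 ± 0.64 and Aif1 at 0.12 ± 0.23, while Ecel1 stood at 2.01 ± 0.41 and Gfap at 0.52 ± 0.17.

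**Figure D3:**
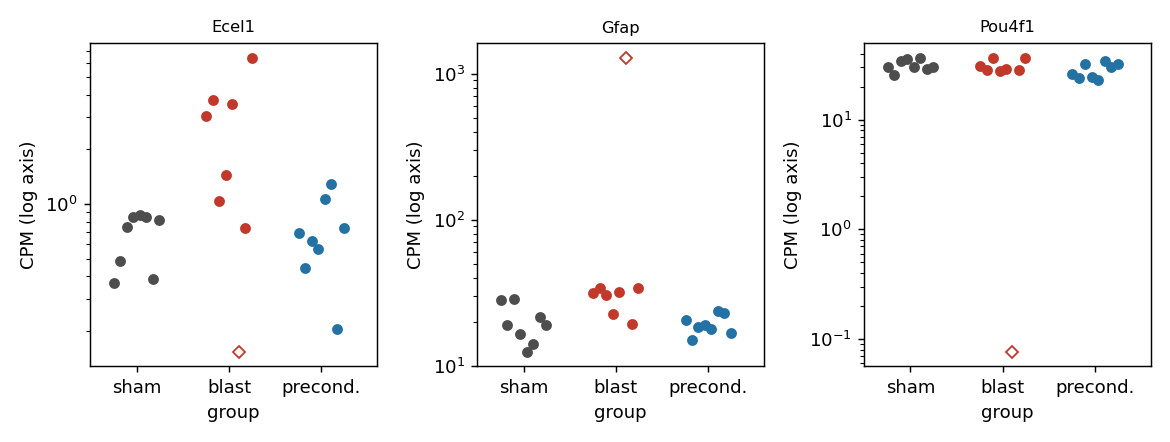
CPM of Ecel1, Gfap and Pou4f1 per library (log axis) by group, scaled over all 24 libraries. Circles are libraries and the open diamond is blast replicate 6, where Gfap reaches 1281 CPM while Ecel1 is at 0.154 and Pou4f1 at 0.0769 CPM. In 6 of the 7 other blast libraries Ecel1 is above every sham library.

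Of the 41 gene lists, camera with the preset correlation called 27 in blast against sham with 24 libraries, 18 higher and 9 lower. Without blast replicate 6 it called 14, 13 higher and 1 lower, and 12 were called in both fits, all in the same direction. No list passed in this contrast with an estimated correlation, with fry or with the exact permutation test, with 24 or 23 libraries. The microglia and macrophage list was higher, with a median log2 fold change of 3.72 with 24 libraries and 0.54 with 23, where 21 of its 23 members were higher (adjusted p = 6.38e-13, and adjusted p = 0.439 with an estimated correlation). The gliosis list had a median of 0.21 with 19 of 23 members higher (adjusted p = 3.00e-06, and adjusted p = 0.476 with an estimated correlation), and the list of the injured ganglion cell and axon response had a median of 0.10 with 14 of 20 higher (adjusted p = 1.20e-05, and adjusted p = 0.105 with an estimated correlation). Members that passed when adjusted over the list alone were Ctss, C1qb, Laptm5 and Tyrobp for microglia, Gfap and Cebpd for gliosis, and Ecel1 and Mmp12 for injury. No member passed over all genes tested. Also higher without blast replicate 6 were nuclear-encoded oxidative phosphorylation (56 of 56 members, median 0.05), mitochondrial-encoded genes (13 of 13, median 0.08), cytosolic ribosomal proteins (60 of 61, median 0.05), interferon response (28 of 29, median 0.22), antigen presentation (15 of 17, median 0.23), complement (19 of 21, median 0.31), cytokines and chemokines (9 of 11, median 0.15), the unfolded protein and integrated stress response (17 of 21, median 0.03), Müller glia identity (14 of 18, median 0.07) and blood (5 of 6, median 1.54). The hypoxia and glycolysis list was lower, with 2 of 24 members higher and a median of -0.04. The retinal ganglion cell list was lower with 24 libraries (median -0.19, adjusted p = 7.56e-04) and did not pass with 23 (median -0.02, adjusted p = 0.519).

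Blast replicate 5 was the shallowest library and had the highest score of the microglia list among the 7. It also had the highest scores among them of the blood (4.62, the others at most 1.82) and pigment (6.47, at most 4.87) lists. The same held for the ciliary body (5.36, at most 3.62) and pericyte (4.81, at most 3.80) lists. When blast replicate 5 was left out as well, 12 lists were called, of which 6 were among the 14, and none passed with an estimated correlation (smallest adjusted p = 0.345). The microglia median was then 0.17 with 18 of 23 members higher (adjusted p = 1.49e-05), the gliosis median was 0.06 with 13 of 23 higher and the injury median 0.06 with 13 of 20 higher. The medians of the interferon list (-0.00091, 14 of 29 higher), the antigen presentation list (-0.026, 6 of 17), the complement list (0.0011, 11 of 21) and the blood list (0.036, 3 of 6) went to near 0. These lists (adjusted p = 0.659, 0.834, 0.747 and 0.659) and the cytokine (0.290), ribosomal protein (0.0850), Müller glia identity (0.145) and hypoxia (0.0571) lists no longer passed. Newly called were the rod (adjusted p = 0.00288) and histone (0.0148) lists, which were higher in blast, and the pericyte (0.0203), fibroblast (0.0231), ciliary body (0.0350) and circadian clock (0.0186) lists, which were lower.

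The comparison of preconditioned with blast retinas asks what a 5 PSI wave before the 20 PSI wave changed. Without blast replicate 6, Ecel1 measured 0.704 ± 0.343 CPM in preconditioned retinas (SD, n = 8), a log2 fold change of -2.03 ± 0.39 against the 7 blast libraries. Gfap measured 19.3 ± 3.02 CPM (SD, n = 8), a log2 fold change of -0.60 ± 0.16. With all 24 libraries these values were -1.84 ± 0.48 for Ecel1 and -3.40 ± 0.82 for Gfap (adjusted p = 0.192 each). The ganglion cell genes Pou4f1, Pou4f2, Thy1, Sncg, Nefl and Rbpms had log2 fold changes from -0.13 to 0.02 with 23 libraries and from -0.10 to 0.13 with 24. None passed edgeR's test, with adjusted p values of 0.598 for Ecel1 and 0.926 for Gfap.

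No gene passed in preconditioned against blast with 24 libraries, where the smallest adjusted p was 0.192 and 2104 genes had an unadjusted p under 0.05, 1873 of them lower in preconditioned retinas, against 995 by chance. With 23 libraries 731 genes had an unadjusted p under 0.05, of which 429 were lower, against 1004 by chance. DESeq2 called 0 genes with 24 libraries and 1 with 23, again Ecel1, at an adjusted p of 0.00257, and over all alternatives the adjusted p of Ecel1 in this contrast ran from 0.00257 to 0.778. With 24 libraries the genes with the smallest p were Mmp12, Atp2a1, H19, Mag, Col14a1, Itgb2, Ckm, Acta1, Sfrp2 and Ctss, with log2 fold changes from -7.36 to -4.12 and an adjusted p of 0.192 each. In the 23-library fit the muscle genes Atp2a1, Acta1 and Ckm had log2 fold changes of 0.13, 0.06 and -0.29, and the collagen gene Col14a1 had 0.14. H19, Mag and Sfrp2 had -0.15, -0.14 and -0.32, and the macrophage genes Mmp12, Itgb2 and Ctss had -1.14, -0.56 and -0.40. With 23 libraries the genes with the smallest p after Ecel1 were Mrpl34, Mro, Tspan2, Drd5, Gfap, Ly6c1, Selplg, Cdk2ap2 and Smim6. The mitochondrial ribosomal protein gene Mrpl34 had a log2 fold change of -0.26 ± 0.06, the tetraspanin Tspan2 -0.35 ± 0.09, the dopamine receptor Drd5 -0.58 ± 0.16, the endothelial gene Ly6c1 -0.37 ± 0.10, Selplg -0.46 ± 0.13, Cdk2ap2 -0.26 ± 0.07, Smim6 -1.10 ± 0.32 and Mro 0.84 ± 0.21, all with an adjusted p of 0.926. Aif1 had -0.52 ± 0.25. With 24 libraries the log2 fold changes were -0.24 for Mrpl34, -1.72 for Tspan2, -0.41 for Drd5, -1.21 for Ly6c1, -2.33 for Selplg, -0.15 for Cdk2ap2, -0.99 for Smim6, 0.36 for Mro and -3.29 for Aif1. With blast replicate 5 left out as well, Ctss was at -0.18 ± 0.09, Itgb2 at -0.22 ± 0.22 and Aif1 at -0.29 ± 0.23, and the signs of H19 (0.37 ± 0.35) and Mag (0.27 ± 0.33) turned.

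Camera with the preset correlation called 26 lists in preconditioned against blast with 24 libraries, 10 higher and 16 lower, and 14 with 23 libraries, 4 higher and 10 lower. Of the 10 lists called in both fits, 7 had the same direction. None passed in either fit with an estimated correlation, with fry or with exact permutation. The unfolded protein and integrated stress response list was lower in both, with a median of -0.21 and -0.10, and 3 of 21 members were higher in the 23-library fit (adjusted p = 3.09e-06, and adjusted p = 0.423 with an estimated correlation). Its members Hspa5, an endoplasmic reticulum chaperone, and Xbp1, a transcription factor of the same response, had log2 fold changes of -0.19 ± 0.07 and -0.20 ± 0.07. The injury list was lower (median -0.06, adjusted p = 0.00601, and adjusted p = 0.423 with an estimated correlation), and Ecel1 alone passed when adjusted over that list. With 23 libraries, mitochondrial-encoded genes (0 of 13 higher, median -0.07), nuclear-encoded oxidative phosphorylation (4 of 56, median -0.04), cytosolic ribosomal proteins (15 of 61, median -0.01), heat shock (4 of 16, median -0.07), replication-dependent histones (2 of 8, median -0.26), retinal ganglion cell (3 of 24, median -0.10), rod photoreceptor (2 of 24, median -0.07) and amacrine cell (5 of 21, median -0.06) lists were lower. The pigment epithelium and melanocyte list (19 of 19 higher, median 0.52), the fibroblast list (20 of 21, median 0.32), the list of ciliary body, iris and cornea (12 of 15, median 0.39) and cholesterol synthesis (15 of 21, median 0.03) were higher. The microglia list had a median of -3.56 with 24 libraries and -0.16 with 23, where it did not pass (adjusted p = 0.0503). For the retinal ganglion cell list the adjusted p was 0.890 with an estimated correlation and 23 libraries.

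Leaving out blast replicate 5 as well gave 16 lists in preconditioned against blast, and none with an estimated correlation (smallest adjusted p = 0.563). The microglia median turned to 0.099 with 14 of 23 members higher (adjusted p = 0.533). The injury list (median -0.024, adjusted p = 0.0882), the ribosomal protein list (median 0.0072 with 37 of 61 higher, adjusted p = 0.508) and cholesterol synthesis (median 0.010, adjusted p = 0.365) no longer passed. The medians of the pigment, ciliary body and fibroblast lists went to 1.14, 1.11 and 0.50, those of the rod and mitochondrial-encoded lists to -0.12 and -0.11. Newly called were antigen presentation (adjusted p = 0.00142), complement (0.0132), interferon response (0.0237) and oligodendrocyte (0.0258) lists, higher in preconditioned retinas, and synapse genes (0.00327), which were lower.

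The comparison of preconditioned with sham retinas sets groups side by side that shared the first pressure and differed in the second. Of the pigment epithelium and melanocyte list, markers of pigmented tissue, 19 of 19 members had positive log2 fold changes, with a median of 0.76 in both fits. The call of this list did not hold with an estimated correlation (adjusted p = 0.605 with 23 libraries). Its scores (mean log2 CPM, scaled over all 24 libraries) overlapped widely between the groups. They ran from 1.06 to 5.89 in sham and from 2.48 to 6.42 in preconditioned libraries. Members of a list can vary together, so 19 of 19 does not stand for 19 separate results. The list members Stra6 and Rdh5, genes of retinoid handling, had log2 fold changes of 0.95 ± 0.51 and 1.15 ± 0.63 with 23 libraries. The retinal ganglion cell list was lower, with 2 of 24 members higher and a median of -0.10 with 23 libraries, and it did not pass with an estimated correlation either (adjusted p = 0.605). Ecel1 measured 0.674 ± 0.222 CPM in sham and 0.704 ± 0.343 CPM in preconditioned retinas, and Gfap measured 19.9 ± 5.91 and 19.3 ± 3.02 CPM (SD, n = 8 each).

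No gene passed in preconditioned against sham in edgeR's test, with a smallest adjusted p of 1.00 with 24 libraries and 0.979 with 23. An unadjusted p under 0.05 was reached by 152 and 530 genes, against 995 and 1004 by chance, and DESeq2 called 0 genes in both fits. With 24 libraries the genes with the smallest p were Mrpl34, Mxi1, Il12a, Rdh1, Slc39a5, Tspan33, Espnl, Tmem53, Otos and Uba6. Mrpl34 (ENSMUSG00000034880, chromosome 8 from 71464959 to 71465747) had a log2 fold change of -0.25 ± 0.06, from 20.1 ± 1.93 CPM in sham to 16.9 ± 1.41 CPM in preconditioned retinas. The MYC antagonist Mxi1 had -0.24 ± 0.06, the interleukin gene Il12a -0.72 ± 0.20, Tspan33 -0.19 ± 0.06 and the ubiquitin-activating enzyme Uba6 -0.16 ± 0.06. The retinol dehydrogenase Rdh1 had 1.05 ± 0.31, the zinc transporter Slc39a5 0.60 ± 0.20, Espnl 0.59 ± 0.20, Tmem53 0.42 ± 0.14 and Otos 0.62 ± 0.22. With 23 libraries the smallest p values belonged to Mrpl34, Pfkfb3, Mxi1, Cep85, Il12a, Dhx29, Alg14, Rdh1, Banp and Nde1. The glycolytic regulator Pfkfb3 had a log2 fold change of -0.24 ± 0.06, Cep85 -0.18 ± 0.05, the helicase Dhx29 -0.17 ± 0.05, Banp -0.23 ± 0.07, the glycosylation gene Alg14 0.27 ± 0.08 and Nde1 0.15 ± 0.05. The ganglion cell genes Rbpms, Pou4f1, Pou4f2, Thy1, Sncg and Nefl had log2 fold changes from -0.16 to -0.03 with 23 libraries, and Aif1 had -0.17 ± 0.24.

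Camera with the preset correlation called 13 lists in preconditioned against sham with 24 libraries, 10 higher and 3 lower, and 20 with 23 libraries, 13 higher and 7 lower. The 12 lists called in both fits had the same direction. None passed with an estimated correlation, with fry or with exact permutation, and with pigment and crystallin scores as covariates 10 lists were called with 23 libraries. With 24 libraries the higher lists were pigment epithelium and melanocyte (adjusted p = 4.96e-09), the opsin, retinoid and visual cycle list (1.85e-05), gliosis (0.00486), cholesterol synthesis (0.00518), blood (0.00933), antigen presentation (0.0253), interferon response (0.0253), the list of ciliary body, iris and cornea (0.0299), microglia (0.0334) and complement (0.0334). The lower ones were hypoxia and glycolysis (0.00606), heat shock (0.0202) and retinal ganglion cell (0.0334). With 23 libraries the adjusted p was 2.73e-06 for the pigment list, 2.69e-05 for the retinal ganglion cell list, 4.27e-05 for the hypoxia list with a median of -0.09, and 4.27e-05 for the microglia list with 22 of 23 members higher and a median of 0.21. Synapse genes (2 of 31 higher, median -0.07) and rod (1 of 24, median -0.06), amacrine (5 of 21, median -0.07) and unfolded protein response (5 of 21, median -0.04) genes, lower in preconditioned retinas, passed only in the 23-library fit. Cytokine (9 of 11 higher), fibroblast (19 of 21), oligodendrocyte (10 of 11) and proliferation (14 of 17) lists, higher in preconditioned retinas, also passed only in that fit. Pfkfb3 alone passed when adjusted over its list. For the hypoxia and microglia lists the adjusted p was 0.605 with an estimated correlation and 23 libraries. The count of 13 fell to 6 without preconditioned replicate 2 or 5, to 7 without preconditioned replicate 1 or sham replicate 6, and to 8 without sham replicate 7.

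A test for any difference among the 3 groups called 160 genes with 24 libraries (edgeR's quasi-likelihood test with 2 degrees of freedom, Benjamini-Hochberg), where 1801 had an unadjusted p under 0.05. It called 0 genes without blast replicate 6, where 432 had an unadjusted p under 0.05, and DESeq2's likelihood ratio test called 0 with 24 libraries, where 1021 did. DESeq2 replaced outlying counts by default, so its values with 24 libraries do not carry blast replicate 6 in full. Its log2 fold change of Atp2a1 in blast against sham (Wald test fit) was -0.046 with 24 libraries and -0.045 without that library. In edgeR with 24 libraries it was 7.45.

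Fold changes of blast against sham and of preconditioned against sham share the sham libraries. Their Pearson correlation was 0.428 across the 19905 genes with 24 libraries, where genes are not independent replicates, against 0.495 (range 0.456 to 0.543) in 100 simulations of unchanged groups. The covariance was 0.0319 against 0.0589 simulated. Without blast replicate 6 the correlation was 0.313 against 0.480 simulated (0.419 to 0.539), and the covariance 0.0113 against 0.0288. With the sham group divided at random into sets of 4, one for each contrast, the mean correlation was 0.0964 with 24 libraries and -0.146 with 23. No gene was called in either contrast, so that no overlap of calls could be counted.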

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

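The tests of blast replicate 6 and of the crystallin share were chosen after the result was seen, and those of the microglia and injury genes before their results were seen.

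In 85 of 288 groups of values tested, 1 library of a group lay far from the rest by Dixon's test at 95%. For normally distributed values chance alone gives that in about 5% of groups. Blast replicate 6 was that library in 66 cases and other libraries in 19. The genes tested here were the named ones, many of them named for a small p in the fit that includes blast replicate 6. Its cases among those genes were therefore fixed in part by that choice.

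Blast replicate 6 stood apart in list scores (mean log2 CPM). Values were retinal ganglion cell 1.69, injured ganglion cell and axon response 4.55, Müller glia and astrocyte gliosis 6.20, Müller glia identity 6.09, astrocyte 6.51, microglia and macrophage 7.67, cytokine and chemokine 6.23, interferon response 5.21, antigen presentation 6.82, complement 6.19, rod photoreceptor 1.76, cone photoreceptor -0.089, bipolar cell -0.91, amacrine cell 1.302 and horizontal cell 0.73. Further values were endothelium 6.63, fibroblast and extracellular matrix 10.82, oligodendrocyte and optic nerve 7.79, skeletal muscle 8.27, immediate early 4.58, circadian clock 4.75, unfolded protein and integrated stress response 6.33, oxidative stress and Nrf2 6.63, apoptosis, necroptosis and pyroptosis 5.19, hypoxia and glycolysis 6.28, cytosolic ribosomal protein 8.53, synapse 1.92, histone (replication-dependent) 1.12 and proliferation 5.14.

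It stood apart in log2 CPM of named genes as well. Gene values were Mmp12 8.38, Mpeg1 10.06, H19 9.45, Atp2a1 10.01, Itgb2 7.55, Tlr13 6.11, Mag 8.18, Lox 9.47, Col10a1 7.76, Ctss 10.48, Pcdh18 5.26, C1qb 8.99, Selplg 6.29, Adgrl4 6.36, Grin2c -4.15, Galnt1 7.29, Phtf1 5.65, Gfap 10.32, Pou4f1 -2.91 and Pou4f2 -2.91. Further gene values were Sncg 3.12, Nefl 0.45, Aif1 4.82, Col14a1 8.69, Ckm 8.02, Acta1 9.17, Sfrp2 7.09, Mro 0.96, Tspan2 6.61, Drd5 -2.91, Ly6c1 6.01, Cdk2ap2 3.90, Pfkfb3 7.01, Dhx29 4.90, Alg14 4.70, Banp 3.95 and Nde1 6.08.

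In other libraries, the crystallin share of counts stood apart in sham replicate 2 (5.98%), blast replicate 7 (3.73%) and preconditioned replicate 2 (11.2%). List scores stood apart for injured ganglion cell and axon response in preconditioned replicate 2 (2.88), ciliary body, iris and cornea in preconditioned replicate 2 (5.70), circadian clock in sham replicate 5 (6.17), mitochondrial-encoded in preconditioned replicate 2 (8.74) and cytosolic ribosomal protein in preconditioned replicate 2 (7.72). The log2 CPM of single genes stood apart for Ltf in sham replicate 7 (-2.53), Col10a1 in sham replicate 8 (-4.15), Col10a1 in preconditioned replicate 5 (-2.97), Selplg in preconditioned replicate 4 (0.98), Grin2c in sham replicate 5 (2.72), Phtf1 in sham replicate 7 (5.31), Slc39a5 in preconditioned replicate 8 (-1.01), Espnl in preconditioned replicate 1 (-1.42), Tmem53 in sham replicate 8 (0.72), Uba6 in sham replicate 3 (4.82) and Pfkfb3 in preconditioned replicate 1 (5.32).

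The first pattern weighed was blast replicate 6. A library made only of a retina that had lost its photoreceptors was excluded, since the amacrine list had a median log2 ratio of -3.92 to the other blast libraries. A mixture of such a retina with other tissue was not excluded, since other tissue lowers the share of every retinal list. An exchange of labels with another group was excluded as its source, since the nearest sham or preconditioned library lay 8.69 log2 units away in rod score; whether the label itself is right was not tested. A library made mostly of tissue other than retina fits, with a median log2 ratio of 6.11 for the fibroblast list. Whether that tissue was dissected in place of retina or replaced the retina of an injured eye could not be separated here, and no biological explanation was tested.

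The second pattern was the crystallin share above 1% in 8 libraries. Lens tissue carried over in dissection fits, since 0 of the 8 had a score of other lens genes within the range of the libraries below 1%. Induction by the 20 PSI wave alone was excluded, as 3 sham libraries were among the 8.

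The third pattern was the higher microglia and injury scores of the 7 other blast libraries. With pigment and crystallin scores as covariates the microglia difference went from 0.37 to 0.36, the injury difference from 0.26 to 0.25 and that of log2 CPM of Ecel1 from 1.73 to 1.70, so that these scores did not account for them (exact permutation p with covariates 0.0284, 0.0214 and 9.32e-04). Mean pigment scores were 3.80 in sham and 3.85 in the 7 blast libraries, and mean crystallin scores 3.94 and 3.71. With groups this alike in both scores, adjustment could change the differences little. The lists and Ecel1 were chosen for being higher in blast, and the p values with covariates are not adjusted for that choice. Scores of blood and other tissues were not covariates. Without covariates the exact permutation p was 0.168 for microglia and 0.0325 for injury, which were chosen for being higher in blast, it was 0.993 for both after Benjamini-Hochberg adjustment over the 41 lists, and edgeR's adjusted p of Ecel1, a member of the injury list, was 0.434. One library alone could account for the microglia difference, which was 0.15 without blast replicate 5, but not for the injury difference, which was 0.19 without the same library. In sham, the 7 blast and preconditioned libraries the microglia score was 1.33 ± 0.36, 1.70 ± 0.61 and 1.63 ± 0.39 (SD). The injury score was 2.26 ± 0.15, 2.52 ± 0.26 and 2.37 ± 0.23. For the microglia and injury scores an effect of 20 PSI that does not depend on the first wave stayed open. An effect of 20 PSI that a 5 PSI wave prevents stayed open, as did an effect of the missing 5 PSI wave alone, since no group analysed here had 0 PSI first without 20 PSI second.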

How the results depend on the processing

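Counts of genes past the threshold stayed at 0 in all 3 contrasts under every alternative fixed before the data were examined and without each library in turn. In the simulations, which changed no gene of low expression, the power to see changes under 1.5-fold was low with 24 libraries. The pairs counted as 2 reads add noise at low counts. Alternatives that leave out blast replicate 6 on top of another change, those with pigment and crystallin covariates and those that leave out further libraries were chosen after seeing the data. A sex term was not run, as all libraries were of one kind (Xist at most 0.955 CPM, Ddx3y at least 55.7 CPM). No paired analysis was possible because the replicate numbers follow the order of the samples only.

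DESeq2 without blast replicate 6 called 1 gene in blast against sham and 1 in preconditioned against blast, Ecel1 in both. The cause was not tested. The test for any difference called 0 genes with no filter, 0 with DESeq2's likelihood ratio test and 0 without blast replicate 6, against 160. Counts of lists were 0 in each contrast with an estimated correlation, fry or exact permutation, with and without blast replicate 6, and 0 with an estimated correlation and blast replicates 5 and 6 left out; the cause was not tested. With 1 surrogate variable 15 lists were called in blast against sham, and with no filter 3 in preconditioned against sham; the cause was not tested. With pigment and crystallin covariates and without blast replicate 6, 17, 14 and 10 lists were called in the 3 contrasts, against 14, 14 and 20 without the covariates. With blast replicates 5 and 6 left out the counts were 12, 16 and 22. Without each library in turn, list counts ran from 14 (without blast replicate 6) to 30 (without blast replicate 1) in blast against sham, from 14 (without blast replicate 6) to 30 (without preconditioned replicate 5) in preconditioned against blast and from 6 (without preconditioned replicate 2) to 20 (without blast replicate 6) in preconditioned against sham. The correlation of fold changes was 0.0964 with the sham group divided into sets of 4, 0.313 without blast replicate 6 and -0.146 with both. The sets share no sham library, which removes the shared part from the first value, and the cause of the others was not tested.

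Of 3087 comparisons of named genes with an alternative, 2963 kept their direction and side of the threshold, 2 passed it newly (Ecel1) and 122 changed sign, none with an adjusted p under 0.05. Of the sign changes, 42 came in settings that keep blast replicate 6, and the rest in settings that leave it out. Leaving out blast replicate 6 alone turned genes such as Atp2a1, Col10a1 and Pcdh18 in blast against sham. The cause of the other sign changes was not tested. With voom and sample weights, the log2 fold changes that turned were H19 -0.062, Mag -0.046, Pcdh18 -0.24, Thy1 0.00980 and Nefl 0.033 in blast against sham, and Atp2a1 0.092, Mag 0.17, Col14a1 0.34, Acta1 0.12, Pou4f1 -0.086, Sncg -0.067 and Nefl -0.10 in preconditioned against blast. With voom and without blast replicate 6, the log2 fold changes that turned were H19 -0.075, Mag -0.057, Pcdh18 -0.24, Thy1 0.010 and Nefl 0.043 in blast against sham, and Atp2a1 0.10, H19 0.00503, Mag 0.18, Col14a1 0.35, Acta1 0.13, Pou4f1 -0.094, Sncg -0.070 and Nefl -0.11 in preconditioned against blast. With blast replicates 5 and 6 and preconditioned replicate 2 left out, the log2 fold changes that turned were H19 -0.12, Mag -0.21, Lox -0.00358, Col10a1 -0.064, Pcdh18 -0.23, Pou4f2 0.00101, Thy1 0.00775 and Nefl 0.064 in blast against sham, and Atp2a1 0.15, H19 0.32, Mag 0.19, Col14a1 0.41, Acta1 0.065, Pou4f1 -0.11, Pou4f2 -0.047, Sncg -0.071 and Nefl -0.12 in preconditioned against blast. With blast replicates 5 and 6 left out, the log2 fold changes that turned were H19 -0.13, Mag -0.22, Lox -0.00691, Col10a1 -0.069, Pcdh18 -0.23, Thy1 0.00396 and Nefl 0.060 in blast against sham, and Atp2a1 0.067, H19 0.37, Mag 0.27, Col14a1 0.42, Acta1 0.044, Pou4f1 -0.14, Pou4f2 -0.088, Sncg -0.11 and Nefl -0.16 in preconditioned against blast. With DESeq2 on 24 libraries, where outlying counts were replaced, the log2 fold changes that turned were Atp2a1 -0.046, Col10a1 -0.00236 and Pcdh18 -0.23 in blast against sham, and Atp2a1 0.13, Col14a1 0.13 and Acta1 0.067 in preconditioned against blast. With DESeq2 and without blast replicate 6, the log2 fold changes that turned were Atp2a1 -0.045, Col10a1 -0.016, Pcdh18 -0.24, Thy1 0.00852 and Nefl 0.022 in blast against sham, and Atp2a1 0.13, Col14a1 0.14, Acta1 0.073, Pou4f1 -0.13, Pou4f2 -0.054, Sncg -0.11 and Nefl -0.12 in preconditioned against blast. With pigment and crystallin covariates and without blast replicate 6, the log2 fold changes that turned were Atp2a1 -0.00519, Pcdh18 -0.24, Thy1 0.014 and Nefl 0.026 in blast against sham, and Atp2a1 0.064, Acta1 0.11, Pou4f1 -0.077, Pou4f2 -0.00650, Sncg -0.054 and Nefl -0.042 in preconditioned against blast. With 1 surrogate variable, the log2 fold changes that turned were Pcdh18 -0.23, Thy1 0.028 and Nefl 0.034 in blast against sham, and Sncg -0.041 in preconditioned against blast, and Pou4f1 0.023, Pou4f2 0.066 and Nefl 0.13 in preconditioned against sham. With DESeq2 size factors, the log2 fold changes that turned were Phtf1 8.53e-05 in blast against sham. With the strict filter, the log2 fold changes that turned were Phtf1 0.00331 in blast against sham.

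Without each library in turn, the ranges of log2 fold changes that crossed 0 were as follows. In blast against sham they were Atp2a1 -0.043 (without blast 6) to 7.64 (without blast 5), Col10a1 -0.016 (without blast 6) to 7.43 (without blast 5), Pcdh18 -0.24 (without blast 6) to 0.44 (without blast 3), Phtf1 -0.15 (without blast 6) to 0.025 (without sham 7), Nefl -0.25 (without blast 3) to 0.024 (without blast 6) and Thy1 -0.043 (without sham 2) to 0.021 (without sham 6). In preconditioned against blast they were Atp2a1 -7.55 (without blast 5) to 0.13 (without blast 6), Col14a1 -6.99 (without blast 7) to 0.14 (without blast 6), Acta1 -5.60 (without blast 5) to 0.064 (without blast 6), Pou4f1 -0.13 (without blast 6) to 0.14 (without blast 8), Pou4f2 -0.055 (without blast 6) to 0.21 (without blast 1), Sncg -0.11 (without blast 6) to 0.13 (without blast 8) and Nefl -0.12 (without blast 6) to 0.15 (without blast 3). In preconditioned against sham they were Rbpms -0.048 (without sham 2) to 0.011 (without sham 5) and Gfap -0.12 (without sham 5) to 0.041 (without sham 1).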

Other observations

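Ecel1, chosen after its values were seen, was the gene with the smallest p in blast against sham and in preconditioned against blast without blast replicate 6. It ranged from 0.368 to 0.871 CPM in sham, from 0.738 to 6.42 CPM in the 7 blast libraries and from 0.203 to 1.295 CPM in preconditioned libraries. The hypothesis that its higher values in blast came from carried-over pigmented or lens tissue was tested with those scores as covariates, and the difference in log2 CPM stayed at 1.70. Mean pigment and crystallin scores were alike in sham and the 7 blast libraries, so that the adjustment could change little. In edgeR's test the adjusted p was 0.434 against sham and 0.598 for preconditioned against blast, and 1 of 40 alternative settings passed the threshold in each contrast. Both contrasts rest on the same 7 blast libraries. With the first pressure held at 5 PSI, preconditioned against sham, the log2 fold change of Ecel1 was 0.048 ± 0.40, and with the second held at 20 PSI, preconditioned against blast, it was -2.03 ± 0.39. Ecel1 was picked as a gene in which the blast libraries stood apart from both other groups, and it did not pass edgeR's test. These values therefore do not decide whether an effect of 20 PSI depends on the first wave. An effect of 20 PSI that a 5 PSI wave prevents and an effect of the missing 5 PSI wave alone were not set apart, since no group analysed here had 0 PSI first without 20 PSI second.

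Whether the counts of calls could come from any grouping of the libraries was tested with 100 divisions, the real one included. For genes, the highest count among the other divisions was 1528 in blast against sham, 1232 in preconditioned against blast and 70 in preconditioned against sham. The real count was 0, which all 100 divisions reach, so that these divisions decide nothing for genes. For lists the real counts of 27, 26 and 13 were reached by 51, 55 and 76 of the 100 divisions, with highest other counts of 33, 34 and 35. Without blast replicate 6 the real counts of 14, 14 and 20 were reached by 39, 49 and 17, with highest other counts of 29, 28 and 26. The 160 genes of the test for any difference were reached by 39 divisions, the highest other count being 1393. Chance could therefore not be excluded for the counts of lists or for the 160 genes. The divisions that called over 1000 genes point to a structure of the samples. That blast replicate 6 alone was its source was tested with 100 divisions of the other 23 libraries, where the highest count of genes in any contrast was 6 against 1528, which fits. All divisions of the 24 libraries held blast replicate 6, yet most called 0 genes in every contrast. The test therefore cannot tell blast replicate 6 alone from that library together with the others placed in its group.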
